A study of Mus musculus with 5 samples.

How the data were processed

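A set of 5 mouse RNA samples of the Balb/c strain had been hybridised to 1-colour Agilent mouse miRNA arrays. The labels marked 3 samples as tumour and 2 as no tumour, and every sample was mapped to a group from its own tumour label. The labels gave a replicate number within each group but no cell type or animal, so p-values measured the spread between these samples, which may be technical. Per the labels' protocols, 100 ng of total RNA per sample was labelled with Agilent's complete labelling method with spike-ins, synthetic RNAs added to each sample in fixed amounts.

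Each array's scanner file was deposited by the authors with linear intensity values, and a value table of the series was deposited as well. Per the file headers, the intensity of each spot had been extracted with Feature Extraction 10.7.3.1 with background subtraction and spatial detrending, and no step had made the arrays comparable with each other. The intensity values of the authors' table equalled the scanner software's total probe signal for 100% of the mouse probe values, within 0.1 percent, over 2990 rows. They were therefore linear, uncentred and not normalized, and with 1 colour a direction does not arise. The medians of its columns were 0.0823, 0.00822 and 0.0137 for the tumour samples and 0.516 and -0.0190 for the no-tumour samples. The annotation in the headers named the mouse build mm9. All 5 arrays lay on 1 slide and in 1 scan.

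Each array held 49324 spots, of which 44880 belonged to 2847 probes for 1122 mouse miRNAs. Probes for 57 viral miRNAs and control spots were kept out of the comparisons. Spots flagged as outliers were left out, which removed between 2.52% and 9.69% of mouse spots per array, and no mouse spot was saturated. The processed signal was averaged over the spots of a probe. A probe counted as detected where a share of at least 0.5 of its spots was well above background. Since under 0.5 of the probes were detected, each array was divided by its 75th percentile over the 52 probes detected on all 5 arrays. These probes covered 33 miRNAs, of which 11 were on the list of short species whose level can follow RNA quality. Values were then raised to a floor, the median over arrays of percentile 1 among detected probes, and put on the log2 scale. The floor stood at 14.4, 27.2 and 20.9 signal units on the tumour arrays and at 128 and 73.8 on the no-tumour arrays. A miRNA was the mean of its probes detected on at least 2 arrays, which left 192 miRNAs and 337 probes, and no miRNA had probes that disagreed in sign by over 0.5 in both directions. miRNA names are those of the array's design.

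The groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, and a miRNA was called at a Benjamini-Hochberg adjusted p under 0.05. Where no array of a group detected a miRNA, the fold is given as "at least", the bright group's mean against the dim group's mean of the higher of each array's lowest detected signal and the miRNA's own. Where a miRNA lay at the floor on every array of a group, detected there or not, the floor makes that group's values equal, and its standard error is too small. eBayes draws the spread of each miRNA towards that of all miRNAs. The equal values can therefore make the standard errors and p-values of other miRNAs too small as well. In the tested set 80 miRNAs lay at the floor on every tumour array, 14 on every no-tumour array and 11 on all arrays. Lists of miRNAs with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over 10 lists. Single values were compared with an exact two-sided permutation test, whose 10 assignments of the arrays cannot give a p below 0.1. The limma fit and the list test were tried on simulated data for this comparison, with 192 miRNAs of which 60 were changed. Changes of 1, 2 and 4 on the log2 scale were recovered for 37.5%, 70.5% and 93.8% of miRNAs, and 4.4% of calls were false. A shifted list was found in 20 of 20 simulations and an unshifted list in 0. The simulated values went through no floor, scaling or filter, and their noise was independent between miRNAs. These figures therefore do not cover miRNAs at the floor or lists whose members vary together.

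The groups, the tests, the lists and the rule for named miRNAs were fixed before the data were examined. The rule took miR-20a-5p and every tested member of the miR-17-92 list, the 10 largest rises and 10 largest falls among called miRNAs whose groups did not overlap, up to 3 tested members with the smallest p of each other list, and the 5 miRNAs with the highest mean. The lists covered the miR-17-92 clusters, endothelial cells, hepatocytes, leukocytes, erythroid cells, epithelium and colon tumour, stellate cells and fibroblasts, inflammation, hypoxia and p53, the let-7, miR-15/16 and miR-30 families, the Dlk1-Dio3 cluster, and short species whose level can follow RNA quality. The alternatives fixed at that stage covered the background correction, signal summary, scaling, filter, floor, variance model, array weights, replicate block, the authors' table, list tests and the omission of each array. After the data had been seen, these were added: scaling to the 4 detected spike-ins, scaling without the RNA quality list, testing only miRNAs detected in both groups, leaving out arrays with the filter recomputed, and taking the spread of a miRNA at the floor in one group from the other group alone. The planned omission of arrays was run with the miRNAs of the full set kept, a choice also made after the recomputed filter had been seen to remove most of them. Figures were drawn with matplotlib.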

Results

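The data were miRNA profiles of 5 Balb/c mouse samples, 3 from the tumour group and 2 from the no-tumour group, each measured on a 1-colour array. The series title places the samples in a study of colon cancer spread to the liver in which miR-20a was delivered to sinusoidal endothelial cells, the cells lining the liver's capillaries. The sample labels themselves named no cell type. Each array carried probes for 1122 mouse miRNAs, and the number of arrays limits the precision of every value. Correlations across miRNAs, which are not independent replicates, ranged from 0.894 to 0.981 among the tumour arrays and from 0.179 to 0.508 across groups, and were 0.767 for the no-tumour pair. They were taken after the floor. It made 80 tested miRNAs equal on every tumour array, 14 on every no-tumour array and 11 on all arrays. This can raise the agreement among the tumour arrays.

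The first comparison asked whether overall miRNA detection differed between the groups. Tumour arrays detected 52, 73 and 92 miRNAs, a mean of 72.3 ± 20.01 (SD, n = 3), and no-tumour arrays detected 206 and 193, a mean of 199.5 ± 9.19 (SD, n = 2). The summed signal of mouse probes was 13.7-fold higher without tumour. It was 43661, 62610 and 61698 units on the tumour arrays against 996877 and 537039 units. Both differences separated the groups completely (exact permutation p = 0.1, the smallest possible). The spike-ins did not separate them, with a geometric mean of 2492 ± 87.2 units (SD, n = 3) in tumour and 2774 ± 407 units (SD, n = 2) without tumour (exact permutation p = 0.2). The control probes hur_1, hur_2, hur_4 and hur_6, whose targets are not given in the sources used here, were 3.11-, 3.83-, 3.19- and 7.82-fold higher without tumour. The scanner software rated no-tumour replicate 1 for evaluation and the other arrays in range.

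**Figure D1:**
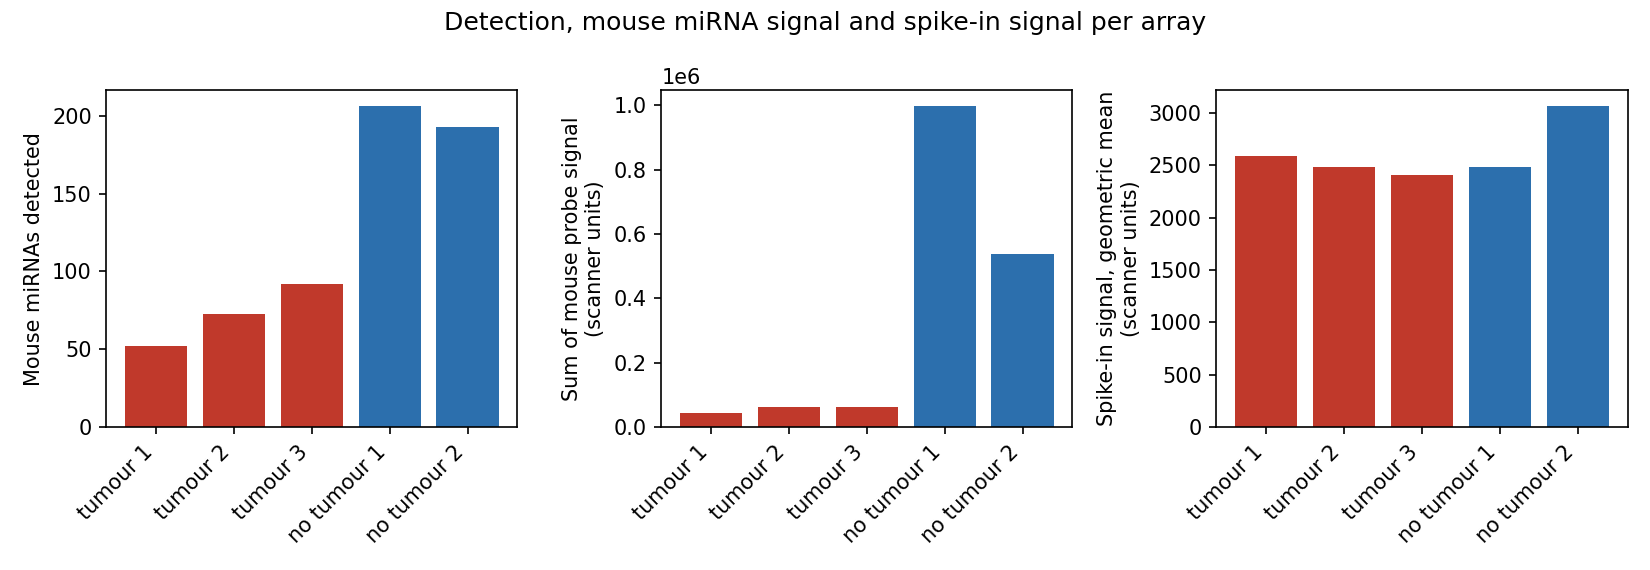
Bars give, for each array, the number of mouse miRNAs detected, the sum of mouse probe signal and the geometric mean of 4 spike-ins, both in scanner units, with tumour arrays in red and no-tumour arrays in blue. Detection ran from 52 to 92 with tumour and from 193 to 206 without, while spike-in signal ran from 2409 to 3062 over all arrays.

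The second comparison concerned miR-20a-5p, the miRNA named in the series title. It was well above background on both no-tumour arrays, at 733 and 568 units, and on 0 of 3 tumour arrays, where it measured 1.06, 1.68 and 1.17 units. In the main setting it was at least 4.30-fold lower in tumour, with a fitted log2 difference of -2.70 (SE 0.150, limma adjusted p = 0.00156). With the spread taken from the no-tumour arrays alone the SE was 0.523 and the limma adjusted p 0.0240. Its probes read CTACCTGCACTATAAGCAC and CTACCTGCACTATAAGCA, and the longer one is placed on chromosome 14 from 115443409 to 115443427. The headers name the build mm9 for the array, and a further position listed for each probe lies inside Mir20a of the GRCm38.p6 gene table, so the position given here is taken to be that of mm9. In that table the miRNA genes beside it, in order of position, are Mir17, Mir18, Mir19a, Mir20a, Mir19b-1 and Mir92-1, with the host gene Mir17hg. The size of the fitted difference depended on the setting where the call was kept, at -0.996 with normexp background correction (adjusted p = 0.0454), -1.54 with quantile normalization, -1.70 with a floor 2 times higher, -4.15 with spike-in scaling, -4.17 without scaling and -4.65 with the total gene signal. The call was lost without background correction (log2 difference -1.01, adjusted p = 0.134) and when the RNA quality list was left out of the scaling (-1.99, adjusted p = 0.105). It was also lost with the replicate block (-2.70, limma adjusted p = 0.119).

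Of 9 tested members of the miR-17-92 cluster and its paralogs, which are known to promote proliferation, 6 fell, 3 did not pass and 0 rose, and 8 passed when adjusted over the list alone. miR-19b-3p was at least 6.48-fold lower (fitted log2 difference -3.29, SE 0.0569, limma adjusted p = 6.37e-05), and miR-20b-5p, miR-93-5p and miR-25-3p were at least 1.63-, 1.49- and 1.17-fold lower. miR-19a-3p was called lower, with no fold bound above 1. With normexp background correction miR-25-3p, miR-93-5p and miR-19a-3p turned to 0.022, 0.15 and 0.16, and without background correction to 0.029, 0.14 and 0.17, and none of them was then called. The members that did not pass were miR-92a-3p at -0.77, miR-106b-5p, at least 1.35-fold lower, and miR-18a-5p, with no fold bound above 1. miR-92a-3p alone was above background on every tumour array, at 85.1 ± 40.9 units (SD, n = 3) against 635 ± 63.5 units (SD, n = 2). The other 8 members were above background on no tumour array and passed the filter only through the no-tumour arrays. This left them little room to rise. The list as a whole was lower (camera adjusted p = 0.0138), which did not hold with an estimated correlation (adjusted p = 0.572). Only miR-19b-3p and miR-20a-5p, 2 of the 6, stayed called with the spread taken from the no-tumour arrays alone. Without background correction the list's median was 0.029 (adjusted p = 0.968).

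**Figure D2:**
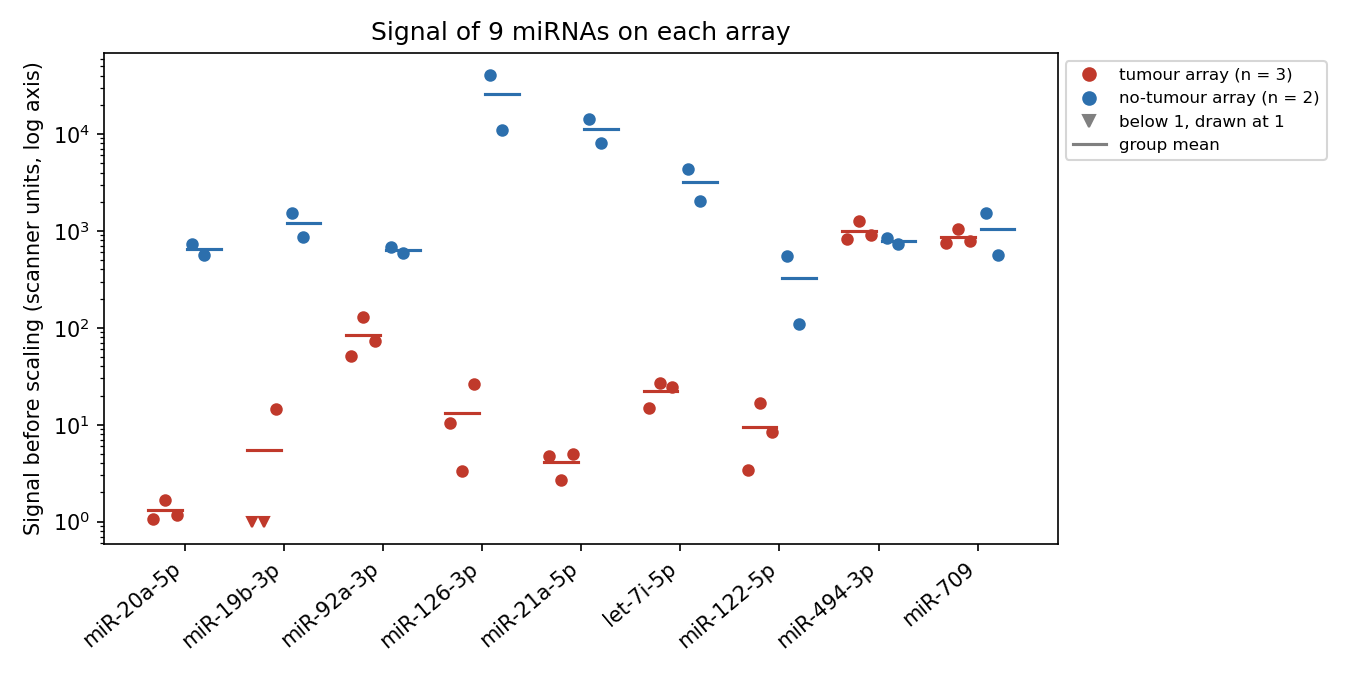
Points give the signal of 9 miRNAs on each array before scaling, in scanner units on a log axis, with tumour arrays in red and no-tumour arrays in blue, lines at group means and triangles for values below 1. miR-20a-5p measured 1.06 to 1.68 units on tumour arrays and 568 to 733 on no-tumour arrays, while the ranges of miR-709 overlapped, at 744 to 1047 units with tumour and 559 to 1519 without.

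Over all miRNAs, 56 of 192 were lower in tumour, 15 were higher relative to the shared probes, and 121 did not pass. The median log2 difference was -0.43 with this scaling, and -1.88 with scaling to the spike-ins. Of the 56 lower miRNAs, 41 were not above background on any tumour array. When only the 91 miRNAs detected in both groups were tested, 15 were lower and 13 higher. The largest falls included miR-126-3p, known for its role in vessel integrity, with a fitted log2 difference of -7.64 (SE 0.391, limma adjusted p = 0.00140), though it was above background on 1 of 3 tumour arrays and the size of its fall rests partly on the floor. miR-21a-5p, often raised in tumours, was at least 66.7-fold lower (limma adjusted p = 2.26e-05). miR-720 at -7.33 and miR-3963 at -5.10 were above background on all 3 tumour arrays. miR-5100, miR-24-3p and miR-3968 were above background on 1 of 3 tumour arrays each, so that their fitted differences of -7.20, -5.44 and -5.38 rest partly on the floor. miR-26a-5p, miR-29a-3p and miR-5097, above background on no tumour array, were at least 29.4-, 28.3- and 20.8-fold lower.

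The largest rises were those of miR-494-3p at 2.57 (SE 0.234, limma adjusted p = 0.00473), miR-5105 at 2.08, miR-709 at 2.07, miR-5622-3p at 1.76 and miR-3098-5p at 1.70. miR-5109 at 1.66, miR-423-5p at 1.29, miR-1895 at 1.21, miR-3072-5p at 1.10 and miR-671-5p at 0.93 followed. miR-3098-5p and miR-671-5p lay at the floor on both no-tumour arrays after scaling, so their differences are set in part by the floor. In the unscaled signal 13 of the 15 had a negative difference, and miR-709 measured 857 ± 165 units (SD, n = 3) in tumour and 1039 ± 679 (SD, n = 2) without. With spike-in scaling 0 miRNAs were called higher and 83 lower by limma, and 103 had an unadjusted p under 0.05. With the spread taken from groups not at the floor, 42 were lower and 5 higher, and with the RNA quality list left out of the scaling 5 were lower and 0 higher. Among the miRNAs with the highest means, miR-3963 and miR-5109 were called, while miR-5126 at 1.67, miR-466i-5p at 2.55 and miR-3960 at 0.84 did not pass.

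**Figure D3:**
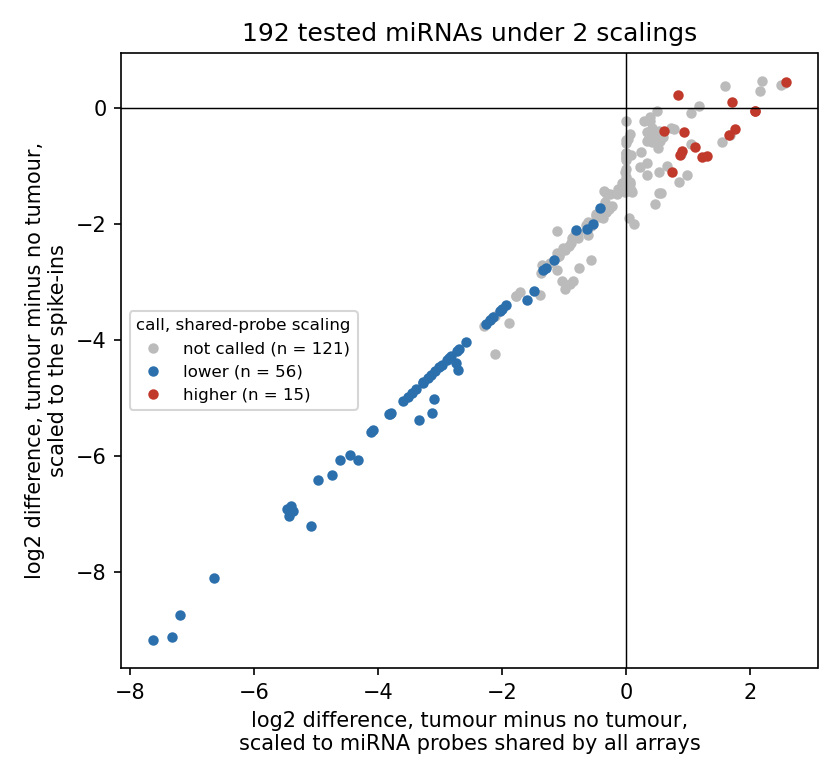
Each point is 1 of 192 tested miRNAs, with the log2 difference of tumour minus no tumour after scaling to shared miRNA probes on the horizontal axis and after scaling to spike-ins on the vertical axis, coloured by the call under the first scaling. Of the 15 miRNAs called higher, 12 lie below 0 on the vertical axis, and all 56 called lower lie below 0 on both.

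The remaining comparisons followed lists of miRNAs across cell types and families. Members above background on no tumour array passed the filter only through the no-tumour arrays, which left them little room to rise. These were 15 of 20 endothelial, 11 of 11 stellate cell and fibroblast, and 5 of 5 leukocyte members. They were also 9 of 10 inflammation, 5 of 6 miR-15/16 and 5 of 5 miR-30 members, but 2 of 9 let-7 members. Where they made up most of a list, a fall was largely set by this filter. Of 20 tested miRNAs abundant or studied in endothelial cells, 12 fell, 8 did not pass and 0 rose (13 lower when adjusted over the list alone), with a median of -2.56 (camera adjusted p = 0.00492). With an estimated correlation the adjusted p was 0.606. Besides miR-126-3p, miR-130a-3p and miR-99a-5p were at least 9.24- and 5.38-fold lower. Of 11 stellate cell and fibroblast miRNAs, 6 fell, 5 did not pass and 0 rose (8 lower when adjusted over the list alone), with a median of -2.83 (camera adjusted p = 0.0226, and adjusted p = 0.606 with an estimated correlation). Among them miR-195a-5p and miR-29c-3p were at least 6.95- and 9.41-fold lower. Of 6 hepatocyte miRNAs 1 fell, miR-22-3p, which many cell types also express and which was at least 16.2-fold lower. miR-122-5p, the most abundant hepatocyte miRNA, measured 9.45 ± 6.67 units (SD, n = 3) in tumour against 330 ± 313 units (SD, n = 2), and miR-101a-3p was at least 2.19-fold lower, neither passing. The list did not pass camera (adjusted p = 0.494), with 1 lower when adjusted over the list alone. All 6 members were above background on no tumour array and 2 lay at the floor in both groups, so this does not show that the list stayed level, and fry, which tests the list against no change, gave a lower list (adjusted p = 0.00534). Of 5 leukocyte miRNAs 2 fell, also 2 when adjusted over the list alone, namely miR-155-5p and miR-146a-5p, at least 2.67- and 3.97-fold lower, while the myeloid miR-223-3p, at least 1.70-fold lower, did not pass (camera adjusted p = 0.142, fry adjusted p = 0.00838). With the spread taken from the no-tumour arrays alone miR-155-5p lost its call (adjusted p = 0.0515).

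Of 10 miRNAs known to rise in inflammation, 6 fell, 4 did not pass and 0 rose, also 6 when adjusted over the list alone, with a median of -2.03 (camera adjusted p = 0.0138, and adjusted p = 0.606 with an estimated correlation). They included miR-21a-5p, miR-155-5p and miR-212-3p, the last at least 3.05-fold lower. In the let-7 family, known for its part in differentiation, 6 of 9 fell and 3 did not pass, also 6 when adjusted over the list alone, with a median of -3.10 (camera adjusted p = 0.0226, and adjusted p = 0.606 with an estimated correlation). The let-7 list also lost its call with the total gene signal (adjusted p = 0.146), the 75th percentile over all probes (0.0705), quantile normalization (0.103), array weights (0.403), spike-in scaling (0.052) and either no-tumour array left out (0.843 and 0.679). The fitted differences of let-7i-5p, -4.74, and let-7e-5p, -2.74, rest partly on the floor, since these were above background on 1 and 2 of 3 tumour arrays, and let-7g-5p was at least 11.3-fold lower. Of 6 members of the miR-15/16 family, known to restrain the cell cycle, 5 fell and 1 did not pass, also 5 when adjusted over the list alone, with a median of -3.14 (camera adjusted p = 0.0278, and adjusted p = 0.606 with an estimated correlation). miR-16-5p and miR-497-5p were at least 11.6- and 4.94-fold lower. In the miR-30 family 2 of 5 fell, and 5 when adjusted over the list alone, with miR-30a-5p and miR-30d-5p at least 6.10- and 2.56-fold lower and miR-30e-5p, at least 2.29-fold lower, not passing (camera adjusted p = 0.158). With the spread taken from the no-tumour arrays alone miR-30d-5p lost its call (adjusted p = 0.0865).

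Among 14 short species whose level can follow RNA quality, 4 rose, 3 fell and 7 did not pass, with the same counts when adjusted over the list alone. miR-494-3p, miR-1895, miR-5105 and miR-5109 were the 4 higher, and miR-5100, miR-3963 and miR-5121 the 3 lower. miR-5121 was named after its value was seen. The list's median was 0.91 and its mean 0.06, and camera placed it above the other miRNAs (adjusted p = 0.00937). fry, which tests the list against no change and not against other miRNAs, did not pass (adjusted p = 0.596). With an estimated correlation the camera adjusted p was 0.606. Among only miRNAs detected in both groups it was 0.0929, so the list's place rests partly on miRNAs undetected in tumour. The median was -1.12 after spike-in scaling, and the medians of all 9 other lists were negative there too, from -5.02 for let-7 to -2.07 for hepatocytes. Of the hypoxia and p53 list 2 members were tested, miR-34a-5p and miR-210-3p, both above background on no tumour array and neither called with this scaling (at least 1.14- and 1.26-fold lower). With spike-in scaling both were called lower, with fitted differences of -2.14 (adjusted p = 0.00735) and -2.38 (adjusted p = 0.00661). Of the Dlk1-Dio3 list 2 were tested, miR-494-3p, which rose as above, and miR-487b-3p, which was detected on both no-tumour arrays (118 and 70.2 units) and on 0 tumour arrays but lay at the floor on all arrays after scaling. Its fitted difference was -1.36 with spike-in scaling, where it was not called (adjusted p = 0.0622), and -1.38 without scaling (adjusted p = 0.0381). No erythroid member was tested, with 1 detected on no-tumour replicate 1 and 0 on the other arrays. All 16 epithelial and colon tumour miRNAs on the array went undetected on all 5 arrays.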

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

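The settings fixed in advance are set beside those chosen after seeing the data, which were spike-in scaling, scaling without the RNA quality list, testing only miRNAs detected in both groups, the recomputed filter and the spread without floored groups. The main counts were 71 changed miRNAs (56 lower and 15 higher), 7 shifted lists and a detection difference of -127.2 miRNAs, tumour minus no tumour. Where no construction is named, the cause of a difference was not tested. Normexp background correction gave 47 changed, 6 higher and 4 lists, with miR-25-3p at 0.022, miR-93-5p at 0.15 and miR-19a-3p at 0.16, turned in sign. The mean signal without background correction gave 46 changed, 35 lower and 2 lists, miR-20a-5p at -1.01, and turned miR-25-3p to 0.029, miR-93-5p to 0.14, miR-19a-3p to 0.17 and the miR-17-92 list's median to 0.029. The scanner software's total gene signal gave 92 lower, 86 were lower from the authors' values, and the 75th percentile over all probes 4 higher, with 94.0% of calls lower against 78.9% in the main setting. Without scaling 103 were lower and 0 higher, and the values turned to -0.44 for miR-671-5p, -0.043 for miR-3098-5p, -0.51 for miR-5622-3p, -0.76 for miR-3072-5p, -0.99 for miR-1895, -0.20 for miR-709, -0.96 for miR-423-5p, -0.19 for miR-5105 and -0.61 for miR-5109. Spike-in scaling gave 83 lower, 0 higher and 1 list, with miR-671-5p at -0.40, miR-5622-3p at -0.36, miR-3072-5p at -0.67, miR-1895 at -0.84, miR-709 at -0.049, miR-423-5p at -0.81, miR-5105 at -0.041 and miR-5109 at -0.46. Scaling without the RNA quality list gave 5 changed, 5 lower and 0 higher by limma, with 43 at an unadjusted p under 0.05 and miR-20a-5p at -1.99. No filter on dim probes gave 20 changed, 19 lower and 1 higher, since 1122 miRNAs were then tested. Requiring detection on all 5 arrays gave 16 changed, 6 lower, 10 higher and 1 list among 33 miRNAs, whose probes also set the scaling. There 37.5% of calls were lower and the median log2 difference was 0.97. Requiring detection in both groups gave 28 changed, 15 lower, 13 higher and 2 lists among 91, with 53.6% of calls lower and a median of 0.42. The excess of falls was thus not kept among miRNAs measured in both groups. A floor 2 times higher gave 42 changed, 35 lower and 7 higher. Array weights gave 46 changed and 1 higher, where the weights' fit stopped before its tolerance was met. The median over shared probes gave 69 lower and 10 higher (87.3% lower), and quantile normalization 52 lower and 20 higher (72.2% lower). Taking the spread without floored groups gave 47 changed, 42 lower and 5 higher, all 47 among the main calls in the same direction, and miR-20a-5p kept its call. The list tests were not rerun with that spread and rest on the same floored values. With an estimated correlation 0 of 10 lists shifted by camera, also 0 at an unadjusted p under 0.05, against 9 by fry. The scanner software's own detection call gave a difference of -148.2 miRNAs.

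Leaving out 1 array at a time with the tested miRNAs kept gave 54 to 104 changed, 42 to 93 lower, 9 to 15 higher without a tumour array and 6 or 11 without a no-tumour array, 6 to 8 lists, miR-20a-5p from -3.10 to -2.09 and detection differences from -137 to -117. The higher count fell to 9 without tumour replicate 3 and to 6 without no-tumour replicate 1, and the lower count rose to 93 without no-tumour replicate 2. When a no-tumour array is left out the lone sample left is assumed to vary like the tumour group, where floored values do not vary at all, so those calls are not a check of stability. The let-7 list then lost its call and its place relative to other miRNAs turned, with medians of -2.87 (adjusted p = 0.843) and -3.19 (adjusted p = 0.679), while with the filter recomputed it stayed called (adjusted p = 0.00241 and 0.00103), and over all omissions its median ran from -3.40 to -2.46. With the filter recomputed, omission of no-tumour replicate 1 left 92 miRNAs with 19 changed, 13 lower, 6 higher and 3 lists, and omission of no-tumour replicate 2 left 86 with 26 changed, 15 lower and 2 lists. miR-20a-5p could not be tested in either, since it was then detected on 1 array. The replicate block gave 0 changed, 0 lower and 0 higher by limma, with 61 at an unadjusted p under 0.05, and miR-20a-5p at -2.70 (adjusted p = 0.119, against a range up to 0.134 over its alternatives). The replicate numbers share no stated origin, so whether they pair the samples is not known. Same-numbered samples deviated in opposite directions (correlations of -0.309 and -0.589 across miRNAs). With 2 no-tumour arrays the deviations mirror each other, so these correlations cannot exclude a pairing. The block also leaves little information on the spread, so its lack of calls does not show that the groups are alike. A slide or scan block was not run, since all arrays shared both. Of 1720 values for other named miRNAs and lists, 1385 kept their side of the threshold, 241 lost the call and 68 gained one. A further 26 changed sign where either fit was called, all 26 given above. Sign changes of values called in neither fit are among the 1385. miR-5126, for example, went from 1.67 to -0.45 with spike-in scaling. Beyond the estimated correlation, the call of the miR-17-92 list was lost in 7 of 25 settings, of let-7 in 7 of 29, of miR-15/16 in 4 of 25, of inflammation in 3 of 25, of stellate cells and fibroblasts in 2 of 25 and of RNA quality in 8 of 29, while the endothelial list lost it in 0 of 28. Signal over background limits the falls, since 97 of 192 tested miRNAs were above background on no tumour array.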

Other observations

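The tests of explanations, the spike-in scaling, the comparisons of viral and hur probes and the relation to GC content were chosen only after the results they bear on had been seen, while camera with either correlation, quantile normalization and the 75th percentile over all probes were planned. Of 57 viral miRNAs with probes on the array, 1, 2 and 2 were detected on the tumour arrays and 3 and 4 on the no-tumour arrays. The brightest probe of mcmv-miR-M23-1-5p measured 788 and 564.7 units on the no-tumour arrays, and the brightest of mcmv-miR-m88-1-3p measured 324.3 and 195.4 units, and neither miRNA was above background on any tumour array. None of the viral probes above background on at least 1 tumour array was higher on every tumour array than on every no-tumour array. Whether these signals came from viral miRNAs or from other RNA bound by the probes was not tested, so they do not show that a virus was present.

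Of the low miRNA signal on the tumour arrays, weaker labelling, hybridization or scanning is argued against by the spike-ins, which differed by -0.148 on the log2 scale (SE 0.15) where the median unscaled miRNA differed by -1.90. Less RNA of the same make-up would lower all miRNAs alike, but 6 of the 33 miRNAs detected on all arrays had a 95% interval that left out their median of -1.29. These 33 share the same arrays and are not independent, and 11 of them belong to the RNA quality list. The count bears only on an equal fall of these 33 and does not exclude less RNA alongside another change. Loss of small RNA, or degraded RNA, in the tumour samples before labelling cannot be told apart from an effect of the tumour. All 9 cell type and family lists had negative medians after spike-in scaling, which either could give. In each list but let-7, most tested members were above background on no tumour array, which itself favours a negative median. No RNA integrity value was used here to separate loss or degradation from a tumour effect. The RNA quality list cannot decide this. It stood above the other miRNAs (camera adjusted p = 0.00937, adjusted p = 0.606 with an estimated correlation, and adjusted p = 0.0867 after spike-in scaling). Yet 1 of its 14 members was above background on no tumour array, against 97 of 192 tested miRNAs, which itself favours that place. Among miRNAs detected in both groups the camera adjusted p was 0.0929, and 0.0992 among those detected on all 5 arrays. The list's spike-scaled median was -1.12 against -5.02 to -2.07 for the 9 lists, while 4 hur controls were 3.11- to 7.82-fold lower in tumour. A fall of the miR-17-92 clusters beyond the general fall stays open too, since 8 of 9 members were above background on no tumour array and their differences there are set by the no-tumour level.

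The 15 higher calls depended on the scaling, since 0 stayed called without scaling or with spike-in scaling. Also 0 stayed called with the RNA quality list left out of the shared-probe scaling, though all 15 stayed positive there. Of the 15, 10 were among the 33 miRNAs whose probes set the main scaling, of which 11 were on the RNA quality list. Under the main scaling, array weights kept 1 call and the spread without floored groups 5. Which scaling is right stays open. All 15 stayed positive with quantile normalization, where 14 stayed called, though it also scales an array by its own miRNA signal. They stayed positive too with the 75th percentile over all probes, where 4 stayed called. That percentile falls among undetected probes, since 85 to 379 of 2847 probes were detected per array. It therefore follows background more than miRNA signal. After spike-in scaling 12 of them were negative and 0 stayed called, but the change of scaling alone moves a miRNA above the floor by -2.12 on the log2 scale, which exceeds the rise of 14 of the 15, so this outcome was fixed in advance and does not show which scaling is right. A rise in signal per amount of RNA on the array also stays open, since the mean difference of these miRNAs after spike-in scaling was -0.391 with a 95% interval between arrays from -2.06 to 1.28 (exact permutation p = 0.6).

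Between the 2 no-tumour arrays, miRNAs with an AC repeat in the probe differed by 2.00 to 5.64 on the log2 scale and those without by -4.02 to 4.26. Probes with a shorter AC run counted as without, such as that of miR-468-3p at 4.26, so the overlap depends on the cut-off. As replicate 2 minus replicate 1, the median of the 9 tested miRNAs with the repeat stood 6.43 above that of the others on the log2 scale. For example, miR-466i-5p measured 420 units on replicate 1 and 15048 on replicate 2, and 2690, 2114 and 5050 on the tumour arrays. A signal shared by probes with an AC repeat is a hypothesis that these arrays cannot test, since the group was itself taken from miRNAs seen to differ strongly between them. The spots left out as outliers on no-tumour replicate 2 are argued against, since the difference was 6.41 with them kept. No biological explanation was tested, as both arrays belong to 1 group.

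Across the 192 tested miRNAs, which are not independent replicates, the unscaled difference was less negative where the probe's GC content was higher (r = 0.253, permutation p = 0.00037, and rho = 0.278, permutation p = 6e-05, adjusted p = 0.00012 over 2 relations). The other relation was of GC content with no-tumour replicate 2 minus 1, over 183 miRNAs without an AC repeat (rho = 0.0571, permutation p = 0.443). Since 97 of the 192 were above background on no tumour array, their unscaled difference mostly follows the no-tumour level. The RNA quality list was drawn up as short GC-rich species, so it is not independent of this relation. The 45 miRNAs with the highest GC content, from 64.3% upward, had a median of -1.08 and held 10 of the 15 called higher, while the 52 with the lowest, up to 44.4%, had a median of -2.89 and held 0.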
